A study of Mus musculus with 6 samples.

How the data were processed

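Keratinocytes from the skin of C57BL/6 mouse embryos were profiled on 6 one-colour Affymetrix arrays, in 3 groups of 2 (control, labelled Ovol1 KO, Ovol1/2 DKO), with 2 mice pooled per array per the labels. The labels call the arrays of a group biological replicates. RNA was amplified with a whole-transcript kit and labelled with biotin per the labels' protocols. The deposited values are probe set intensity on a linear scale. Affymetrix Expression Console 1.1.1 and PLIER 2.0, a probe summarisation method, are named in the submitters' processing notes; background correction, normalization and filters are not given in the sources used here.

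The table held 35556 probe sets. A platform annotation gave 1 gene symbol to 21789 of them and several to 1621, and 12146 are unnamed here. Symbols were updated by Entrez identifier against a table of the mouse assembly GRCm38.p6, used for names alone, and 91 identifiers had no match. Probe sets with several symbols were not named. For the 999 genes with several probe sets, the one with the highest mean over the 6 arrays was used, leaving 19938 genes. Of the list symbols, 5 were matched through an older symbol or synonym.

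Values were taken as log2(intensity + 16). A difference on that scale understates the change of dim genes. One linear model over all 6 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes) gave the 3 comparisons, with 3 residual and 3.68 prior degrees of freedom and Benjamini-Hochberg adjustment within each comparison; an adjusted p under 0.05 passed. With 2 arrays against 2, no exact test can give a two-sided p below 0.333, so the tests rest on the spread pooled over genes and groups. Standard errors are those of the moderated fit. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists of a comparison, and again with an estimated correlation; no list passed in any comparison with the estimated correlation.

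Design, alternatives, gene lists and the rule for named genes were fixed before the data were examined. There were 19 lists on mesenchymal, epithelial, junction, basal, spinous, granular, cell cycle, p53, Wnt, TGF-beta and BMP, Notch, actin, inflammation, interferon, cholesterol, hypoxia and hair follicle genes and on genes earlier tied to Ovol factors, and 8 marker lists of other cell types. Named per comparison were Ovol1 and Ovol2 and up to 8 genes per direction with the largest passing change. These needed both arrays of one group above both of the other, a mean in the higher group at or above the median of all genes (7.56), and an ordinary gene symbol. Directions with under 5 such genes were filled to 5 by the smallest p and given as not passing. Each list added up to 4 passing genes, or up to 2 by smallest p where none passed. Genes named outside this rule were chosen after their values were seen: Vim in the first comparison, Zeb1 in the second, Trp63 in the third, Krt5, Krt14, Col1a1, Dcn, Fzd2, and the genes that passed once 1 or 2 arrays were left out.

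Replicate numbers were checked as a possible batch. Among unnamed probe sets, 32.9% had all replicate 1 arrays apart from all replicate 2 arrays, against 10% by chance, and 24.4% of named genes did. Deviations from group means correlated between replicate 1 arrays at 0.261 (control and labelled Ovol1 KO), 0.490 (control and Ovol1/2 DKO) and 0.194 (labelled Ovol1 KO and Ovol1/2 DKO). The labels do not say that a number marks a shared day or litter, so the model without the block was kept and blocked counts are given beside it.

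The fit was tested on simulated data with 50 genes changed at each size among 19938. For Ovol1/2 DKO against control it called 20% of 2-fold and 98% of 4-fold changes, with 16 unchanged genes called. For the arrays labelled Ovol1 KO against control it called 22% of 2-fold and 90% of 4-fold changes, with 19 unchanged genes called, and for Ovol1/2 DKO against labelled Ovol1 KO 20% and 90%, with 9. In each of these single simulations, unchanged genes made up a larger share of the calls than the 0.05 asked. The simulated noise was independent between genes, without deviations that genes of an array share, so these rates may not hold for the real arrays. Expected relations between comparisons that share arrays came from 100 simulations of unchanged groups. Alternatives were a replicate block, leaving out each array, only the groups compared, quantile normalization, median centring, offsets of 1 and 64, leaving out dim genes, all probe sets, an intensity trend, robust variance and array weights. Leaving out the 2 arrays without Xist signal together was added after the data were seen. So was the level called near background.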

Results

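RNA from mouse epidermal keratinocytes was hybridised to 6 Affymetrix gene arrays, 2 for each of 3 genotypes. Keratinocytes, the cells that build the epidermis, were taken from embryonic skin shortly before birth and grown for 2 to 5 days without added calcium, a signal that drives them to differentiate. Ovol1 and Ovol2 are related zinc finger transcription factors expressed in epithelia. The control arrays came from mice that kept at least one working copy of each factor, the arrays labelled Ovol1 KO from Ovol1-null mice, and the Ovol1/2 DKO arrays from Ovol1-null mice that also lost Ovol2 in K14-expressing keratinocytes. Each array held RNA from 2 mice. The stated purpose was to find primary changes, and the design sets each knockout against control and the knockouts against each other. The median intensity per array ran from 103.3 to 109.8 over 35556 probe sets, and 19938 named genes were tested. With 2 arrays per group, the number of arrays limits the precision, and the median standard error of a log2 difference was 0.245.

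The targeted genes were read first. Ovol1 stood at 9.64 and 9.95 (log2) in the control arrays, at 10.75 and 9.80 in the arrays labelled Ovol1 KO, and at 5.96 and 6.22 in the Ovol1/2 DKO arrays. Ovol1 was thus lower in Ovol1/2 DKO than in control (log2 difference -3.70, SE 0.34, n = 2 per group, limma adjusted p = 0.00755), at a level near background. In the arrays labelled Ovol1 KO it lay 0.48 above control (SE 0.34, limma adjusted p = 0.999), against their label, so every direction drawn from these arrays rests on a label that the Ovol1 signal did not bear out. Ovol2 read 8.37 and 6.97 in control, 7.88 and 8.38 in the arrays labelled Ovol1 KO, and 7.63 and 7.50 in Ovol1/2 DKO. It did not differ by the test (Ovol1/2 DKO minus control -0.10, SE 0.45; 0.60 without control replicate 1 and -0.80 without control replicate 2, neither passing), so the loss of Ovol2 in the Ovol1/2 DKO label was not seen in its signal. Where the Ovol1 and Ovol2 probe sets lie relative to the deleted parts is not known here, and a probe set outside a deleted part checks nothing. All 6 samples carry a female label. Xist, the RNA of the inactive X chromosome, read 11.24 in control replicate 2, 10.99 in replicate 2 labelled Ovol1 KO, and 11.43 and 11.28 in Ovol1/2 DKO, but 4.43 in control replicate 1 and 4.54 in replicate 1 labelled Ovol1 KO. The Y-linked gene Eif2s3y read 13.80 in replicate 1 labelled Ovol1 KO and at most 5.14 in the others.

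**Figure D1:**
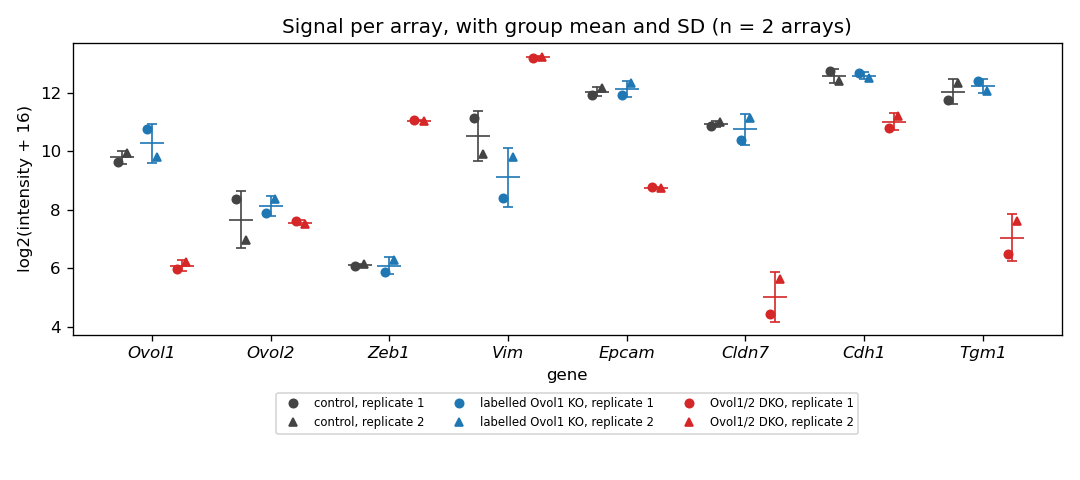
Signal of 8 genes on each array, as log2 of intensity plus 16; circles and triangles are replicates 1 and 2, horizontal marks are group means and bars are SDs (n = 2). Ovol1 is low only in the Ovol1/2 DKO arrays (5.96 and 6.22), where Zeb1 is higher and Epcam, Cldn7, Cdh1 and Tgm1 are lower than in the other arrays. Cdh1 still has a mean of 11.01 there.

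The first comparison set Ovol1/2 DKO against control, by the labels a loss of both factors. Zeb1, a transcription factor that represses epithelial genes, rose in Ovol1/2 DKO (log2 difference 4.95, SE 0.21, n = 2 per group, limma adjusted p = 0.00257). Its control mean of 6.10 lies near background, and the difference ran from 4.21 to 5.29 over the settings tried. The collagen cross-linking enzyme Lox rose 19.0-fold (4.25, SE 0.38), the secreted matricellular protein Ccn4 18.2-fold (4.18, SE 0.24) and the smooth muscle actin-binding protein Tagln 10.3-fold (3.36, SE 0.44). The tight junction protein Cldn7 (log2 difference -5.92, SE 0.43), the amino acid transporter Slc6a14 (-6.59, SE 0.50) and the glutamate transporter Slc1a1 (-6.01, SE 0.33) fell. Their Ovol1/2 DKO means of 5.02, 5.06 and 5.45 lie near background, so the size depends on the processing, from -7.78 to -5.28 over the settings tried for Slc6a14. In all, 403 of 19938 genes passed limma at an adjusted p under 0.05, 124 higher and 279 lower, and 242 of them differed more than 4-fold.

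Among the other genes with the largest changes, the focal adhesion protein Tns1 rose 21.3-fold, Igfbp4 13.8-fold and Fstl1 9.53-fold, and the endocytic adaptor Dab2 by 3.27 (log2) from a control mean of 6.15, near background. Of the other Tns1 probe sets, 4 were higher by 1.52 to 3.40 and the fifth by 0.26, while another probe set of Dab2 gave -0.17. Mal2 (log2 difference -5.63, SE 0.62), Prl2a1 (-5.62, SE 0.80) and the epidermal cytokine Il1f6 (-5.59, SE 0.48) fell to Ovol1/2 DKO means of 5.98, 4.78 and 5.12, again near background. Prl2a1 ran from -6.89 to -4.23 over the settings and lost the call without either Ovol1/2 DKO array. Sprr2d (-5.50, SE 0.98) and Sprr2e (-5.49, SE 0.93) also fell, with uncertain values. Their cluster of near-identical cornified envelope genes may be read by one another's probes, which could not be checked here, and the control arrays lay apart (SD 2.39 and 2.34). Sprr2d ran from -7.19 to -3.81 over the settings, and both lost the call without any 1 of the Ovol1/2 DKO or labelled Ovol1 KO arrays. A lone labelled Ovol1 KO array adds no spread, and both also lost the call with only the groups compared. Their call thus rested on pooling the smaller spread of the labelled Ovol1 KO arrays (SD 0.029 and 0.37).

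Part of the epithelial genes fell. Of 20 measured genes of epithelial identity, 12 fell, none rose and 8 did not pass, with Epcam at -3.28 (SE 0.22, limma adjusted p = 0.00343), the transcription factor Elf3 at -4.14 (SE 0.38) and the membrane protease St14 at -2.97 (SE 0.23) on the log2 scale. Adjusted over the list alone, 17 fell and 1 rose. The list mean was -2.45 (camera adjusted p = 7.05e-26 in limma; adjusted p = 0.0951 with an estimated correlation). Of 17 tight and gap junction genes 8 fell (12 adjusted over the list alone), among them Cldn6 (-3.53, SE 0.31) and, falling to levels near background, Ocln (-3.91, SE 0.32) and Marveld2 (-3.59, SE 0.35). Their mean was -2.22 (camera adjusted p = 3.08e-18; adjusted p = 0.0951 with an estimated correlation). Of 19 adherens junction and desmosome genes 5 fell (6 adjusted over the list alone), including Cdh1, the epithelial cadherin (-1.57, SE 0.24, limma adjusted p = 0.0292), Nectin4 (-3.66, SE 0.45) and Dsc2 (-2.70, SE 0.36). That list had a mean of -0.86 (camera adjusted p = 7.61e-08; adjusted p = 0.151 with an estimated correlation).

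Part of the late differentiation and inflammatory genes fell too. Of 36 granular and cornified layer genes 6 fell and none rose (23 and 0 adjusted over the list alone), with Tgm1, the transglutaminase of the cornified envelope, down 32.0-fold (-5.00, SE 0.41, limma adjusted p = 0.00551) and the lipid transporter Abca12 down 23.0-fold (-4.53, SE 0.35). The list mean was -2.78 (camera adjusted p = 7.05e-26; adjusted p = 0.254 with an estimated correlation). This list also varied within groups: its mean level was 8.79 and 10.18 in the control arrays, 10.59 and 8.95 in the arrays labelled Ovol1 KO, and 6.36 and 7.05 in Ovol1/2 DKO. Of 25 stress keratin and skin inflammation genes 9 fell (17 adjusted over the list alone), among them the antimicrobial peptide Defb14 (-4.36, SE 0.69, to a mean of 4.78 near background), Krt16 (-3.63, SE 0.55) and the prostaglandin synthase Ptgs2 (-1.89, SE 0.27). Their mean was -2.57 (camera adjusted p = 4.64e-24; adjusted p = 0.0740 with an estimated correlation). Of 10 spinous genes, Serpinb2 fell by 3.47 (SE 0.36), with 2 lower adjusted over the list alone. The spinous mean was -0.57 (camera adjusted p = 0.0232; adjusted p = 0.257 with an estimated correlation; 0.0769 with replicate number as a block). No gene of the basal list passed, and its mean was 0.29 over 17 genes (camera adjusted p = 0.0312; adjusted p = 0.635 with an estimated correlation). The basal keratins Krt5 and Krt14 differed by 0.07 (SE 0.19) and 0.07 (SE 0.19) and did not pass.

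Mesenchymal and contractile genes moved the other way, in part. Of 20 EMT and mesenchymal genes, 4 rose, 1 fell and 15 did not pass (7 and 1 adjusted over the list alone). Zeb2, a relative of Zeb1, rose by 2.19 (SE 0.28, limma adjusted p = 0.0183) from a control mean of 5.97, while the transcription factor Foxc2 fell by 3.23 (SE 0.30) to a mean of 4.98, both near background. The intermediate filament gene Vim was 2.70 higher (SE 0.54) but did not pass (limma adjusted p = 0.0730). The list mean was 1.01 (camera adjusted p = 3.04e-06; adjusted p = 0.359 with an estimated correlation). Of 29 actin and focal adhesion genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with Acta2, smooth muscle actin, up by 3.08 (SE 0.33), Actg2 by 3.08 (SE 0.37) and the integrin Itgb6 lower (-1.71, SE 0.21). Their mean was 0.48 (camera adjusted p = 0.00995; adjusted p = 0.626 with an estimated correlation).

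In the signalling lists, Tgfbi rose by 3.17 (SE 0.46), the ligand Tgfb3 rose by 2.08 (SE 0.24) and Inhba fell by 2.48 (SE 0.29) among 26 TGF-beta and BMP genes (5 higher and 2 lower adjusted over the list alone), whose mean of 0.19 did not pass (camera adjusted p = 0.257). The Notch ligand Jag2 rose by 1.30 (SE 0.23, limma adjusted p = 0.0487) among 16 Notch genes (5 adjusted over the list alone), with a list mean of 0.54 (camera adjusted p = 4.75e-04; adjusted p = 0.151 with an estimated correlation). No Wnt gene of 25 passed (4 higher adjusted over the list alone; with replicate number as a block Wnt3a at 1.54 and Dkk3 at 1.40 did, adjusted p = 0.0410 and 0.0347) at a mean of 0.37 (camera adjusted p = 0.0186; adjusted p = 0.254 with an estimated correlation). No cell cycle gene of 33 passed, and the list mean was 0.33 (camera adjusted p = 0.00392; adjusted p = 0.784 with an estimated correlation), but -0.11 without control replicate 2 and 0.02 without Ovol1/2 DKO replicate 1, neither passing, and 0.78 and 0.65 without the other control or Ovol1/2 DKO array. Of 21 interferon response genes Rsad2 fell by 2.23 (SE 0.32) to a level near background, also the only one adjusted over the list alone, with a mean of -0.41 (camera adjusted p = 0.00213; adjusted p = 0.254 with an estimated correlation). Adm fell by 1.97 (SE 0.27) and P4ha1 rose by 1.28 (SE 0.19) among 20 hypoxia and glycolysis genes (1 higher and 2 lower adjusted over the list alone), and Foxn1 fell by 3.08 (SE 0.31), also to a level near background, among 22 hair follicle genes (1 lower adjusted over the list alone). These means of -0.19 and -0.30 did not pass (camera adjusted p = 0.160 and 0.217), and the hair follicle median was 0.02, of the other sign. The p53 list (mean -0.00 over 18 genes, median 0.03, camera adjusted p = 0.837) and the cholesterol synthesis list (mean -0.09 over 14 genes, camera adjusted p = 0.271) held no gene that passed. Of 6 genes with earlier reports of regulation by Ovol factors, Zeb1 rose (2 higher and 1 lower adjusted over the list alone), at a mean of 1.05 (camera adjusted p = 0.112).

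Markers of other cell types were read on the same arrays. Among 12 fibroblast markers Thy1 rose by 1.67 (SE 0.22), while Col1a1 was 0.42 higher (SE 0.37) and Dcn differed by -0.00 (SE 0.48). The fibroblast mean was 0.36 (camera adjusted p = 0.144). The list level was 6.59 and 7.32 in control, 6.69 and 7.40 in the arrays labelled Ovol1 KO, and 7.01 and 7.62 in Ovol1/2 DKO. It was thus higher in replicate 2 of each group, and with replicate number as a block the camera adjusted p was 0.0985. The 9 melanocyte markers had a mean of -0.65 with none passing (camera adjusted p = 0.00615; adjusted p = 0.359 with an estimated correlation). Among 7 Schwann and Merkel cell markers Krt8, also a keratin of simple epithelia, fell by 1.79 (SE 0.28), with a mean of -0.68 (camera adjusted p = 0.00118; adjusted p = 0.359 with an estimated correlation) and 3 lower adjusted over the list alone. The leukocyte, endothelial, skeletal muscle, adipocyte and erythroid means were -0.14, -0.01, 0.03, 0.08 and 0.07, with no gene passing and camera adjusted p values of 0.571, 0.979, 0.979, 0.902 and 0.950. The adipocyte median was -0.01, against a positive mean, and adjusted over the list alone 1 endothelial marker was higher and 1 lower. With replicate number as a block the endothelial marker Kdr passed (-1.15, adjusted p = 0.0363).

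Of the 51 named genes that passed, 19 had a lower group mean at or under 6.20, the highest median of the unnamed probe sets on an array and the level called near background here. Their log2 differences varied over the settings by 0.93 to 3.38. List shifts depended on single arrays too. Without control replicate 1 the actin and basal shifts did not pass (camera adjusted p = 0.0690 and 0.124), without control replicate 2 the spinous shift (0.0599), without Ovol1/2 DKO replicate 1 the spinous and interferon shifts (0.0680 and 0.154), and without Ovol1/2 DKO replicate 2 the basal shift (0.0675).

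The count of 403 depended on the arrays. Zeb1, Cldn7, Epcam and Tgm1 passed in all settings tried for named genes, while Cdh1, Fstl1, Ptgs2 and Krt16 each lost the call without either control array. Of the 51 named genes that passed, 25 did so in every setting that measured them. Among these, Dab2, Foxc2 and Marveld3 were not measured with dim genes left out. The count became 152 without control replicate 2, 109 without Ovol1/2 DKO replicate 1, 99 without Ovol1/2 DKO replicate 2, and 1395 without both arrays that lacked Xist signal, a choice made after the data were seen; with replicate number as a block, since replicate numbers separated the arrays, it was 597 (217 higher, 380 lower), including 396 of the 403.

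**Figure D2:**
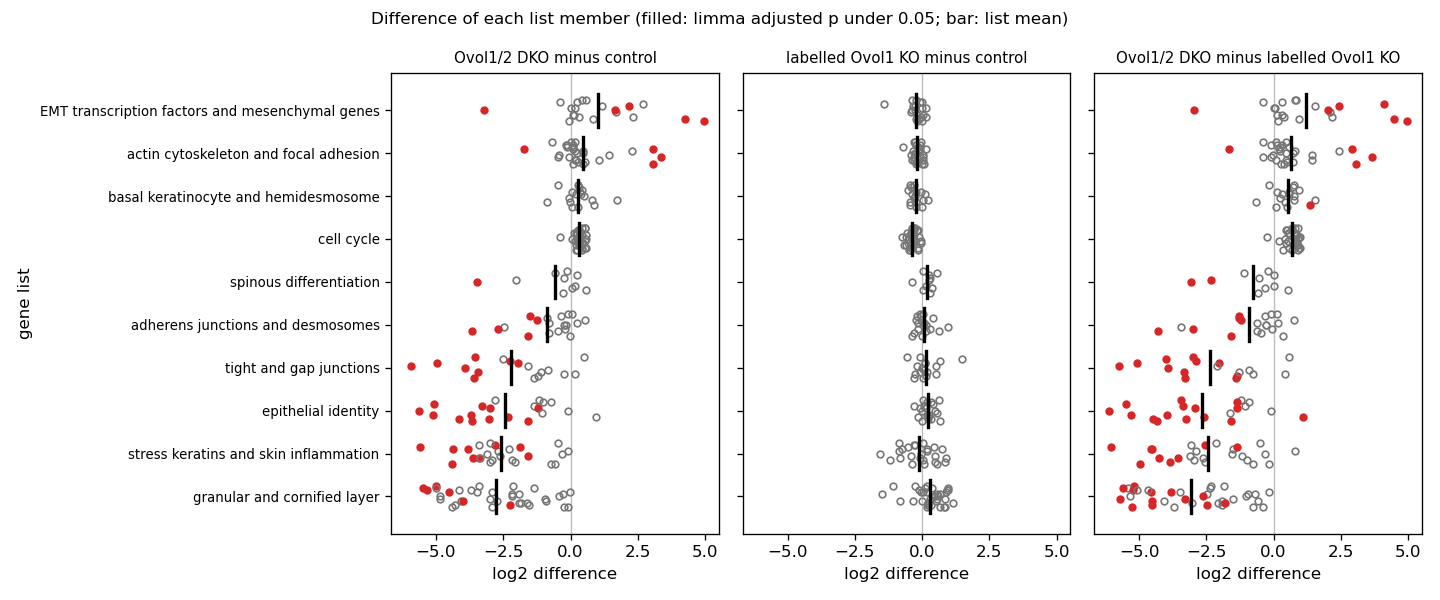
Log2 difference of each member of 10 gene lists in the 3 comparisons; filled points pass limma at an adjusted p under 0.05 and bars are list means. Epithelial identity, junction, inflammation and granular genes lie mostly below 0 in both comparisons with Ovol1/2 DKO, with means of -2.45 and -2.66 for epithelial identity, and no member passes between the arrays labelled Ovol1 KO and control.

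The second comparison, by the labels a loss of Ovol1 alone, gave no gene that passed. Between the arrays labelled Ovol1 KO and control, 0 of 19938 genes had a limma adjusted p under 0.05, and the smallest was 0.999. At an unadjusted p under 0.05 there were 153 genes, against 996.9 by chance. So few means that the fitted spread was large beside the differences between these groups, and 0 passing genes does not show that nothing changed. The granular list, at 8.79 and 10.18 in control and 10.59 and 8.95 in the arrays labelled Ovol1 KO, differed more within groups than between them. Whole arrays did not group by these labels either. Across genes, control replicate 2 correlated at 0.986 and 0.978 with replicates 2 and 1 labelled Ovol1 KO, and control replicate 1 at 0.962 and 0.971. The pairs within control and within labelled Ovol1 KO gave 0.969 and 0.961. The lowest unadjusted p values under the naming rule belonged to the phosphatase Inpp5d (-2.54, SE 0.47) and the receptor Kdr (-1.08, SE 0.22) on the lower side, and to Lamp5 (1.04, SE 0.22) and Vnn1 (1.17, SE 0.25) on the higher side. None of these passed (limma adjusted p = 0.999 for each). Vim was 1.42 lower (log2 difference -1.42, SE 0.54), Zeb1 differed by -0.01 (SE 0.21) and Hes1, a Notch target, by -0.61 (SE 0.23), none passing.

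As groups, 7 of the 27 lists shifted by camera, none with a passing member, over all genes or adjusted over the list alone. The cell cycle list was lower by the test (mean -0.36 over 33 genes, camera adjusted p = 2.99e-06), with Cenpe at -0.73 (SE 0.43) and Cenpf at -0.58 (SE 0.38). The basal list was lower (mean -0.23, camera adjusted p = 5.30e-04), and so were the actin and focal adhesion genes (mean -0.17, camera adjusted p = 0.0112). The granular and cornified list was higher (0.29, camera adjusted p = 0.0195), as were epithelial identity (0.21, 0.0288), spinous (0.19, 0.0256) and interferon (0.16, 0.0256) genes. All 7 had an adjusted p = 0.761 with an estimated correlation. Of the 7, 3 passed without control replicate 1 and 3 without control replicate 2. For the arrays labelled Ovol1 KO, 2 passed without replicate 1 and 6 without replicate 2. Among these passing lists only the granular list had turned, without either replicate 1 array. Without control replicate 1 the granular mean was -0.41, and the cell cycle mean was 0.09, not passing. Without replicate 1 labelled Ovol1 KO the granular mean was -0.53. Spinous at -0.19, actin at 0.03, basal at -0.08 and epithelial identity at 0.02 did not pass there. Of the other lists, the Wnt mean of -0.05 was negative while its test pointed up (camera adjusted p = 0.962). Endothelial markers held 1 gene lower adjusted over the list alone, Kdr. With replicate number as a block again 0 genes passed (715 at an unadjusted p under 0.05), the epithelial identity shift no longer passed (camera adjusted p = 0.0576) and the melanocyte markers did (mean -0.41, camera adjusted p = 0.0459, against 0.0760 without the block). Without replicate 2 labelled Ovol1 KO 3 genes passed, Eif2s3y (8.94), Uty (5.15) and Gsdmc (4.05), the first and second of them Y-linked. Another setting, chosen after the data were seen, left out both arrays that lacked Xist signal. The fitted spread then came from the Ovol1/2 DKO arrays alone, a group outside this comparison, so no count of passing genes is given. On the fixed granular and cornified list, 6 genes picked by that fit were lower: Lce1a1 (-6.00), Lce3c (-3.81), Lce3e (-3.49), Kprp (-3.09), Klk5 (-2.51) and Hrnr (-2.47). The granular mean there was -1.23, opposite to the 0.29 over all arrays, with 1 array per group.

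The third comparison set Ovol1/2 DKO against the arrays labelled Ovol1 KO, which by the labels differ in Ovol2; of the signals of both factors, that of Ovol1 differed. Zeb1 rose (log2 difference 4.96, SE 0.21, n = 2 per group, limma adjusted p = 0.00252; 4.22 to 5.32 over the settings tried, from a mean of 6.08 near background), as did Igfbp4 24.0-fold (4.59, SE 0.26), Lox 22.0-fold (4.46, SE 0.38) and Vim 17.3-fold (4.12, SE 0.54, limma adjusted p = 0.0146). Slc6a14 (-6.26, SE 0.50), Mal2 (-6.11, SE 0.62), Slc1a1 (-6.11, SE 0.33) and Il1f6 (-6.04, SE 0.48) fell to the same levels near background as in the first comparison. Ovol1 itself fell (-4.18, SE 0.34, limma adjusted p = 0.00477), although both groups are labelled Ovol1-null, and Ovol2 did not pass (-0.57, SE 0.45). In all, 628 genes passed limma, 247 higher and 381 lower, and 349 of them differed more than 4-fold.

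Among the other leading genes, Tns1 rose 19.0-fold, Fstl1 18.0-fold, the protease Tll1 17.0-fold and Ccn4 from a mean of 7.36 to 11.36. Sprr2d (-6.78, SE 0.98) and Sprr2e (-6.32, SE 0.93) fell, with the uncertainty of shared sequence, and so did Pdzk1ip1 (-5.94, SE 0.78) and Il1f5 (-5.91, SE 0.91), to Ovol1/2 DKO means of 5.40 and 5.41. Without Ovol1/2 DKO replicate 1, or without replicate 1 labelled Ovol1 KO, these 4 genes lost the call.

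Of 20 epithelial identity genes 14 fell and 1 rose (18 and 1 adjusted over the list alone). Epcam (-3.37, SE 0.22) and Elf3 (-4.49, SE 0.38) fell, while Trp63, the p63 factor of basal keratinocytes, rose, from a mean of 10.30 to 11.40. The mean was -2.66 (camera adjusted p = 6.73e-22; adjusted p = 0.120 with an estimated correlation). Of 17 tight and gap junction genes 11 fell (1 higher and 13 lower adjusted over the list alone), including Cldn7 (-5.73, SE 0.43) and Cldn4 (-3.33, SE 0.35). Their mean was -2.36 (camera adjusted p = 1.37e-15; adjusted p = 0.120 with an estimated correlation). Of 36 granular and cornified genes 13 fell (24 adjusted over the list alone), including Tgm1 (-5.19, SE 0.41), at a mean of -3.06 (camera adjusted p = 2.89e-23; adjusted p = 0.257 with an estimated correlation). Of 25 stress and inflammation genes 9 fell (14 adjusted over the list alone), including Lcn2, which binds iron-carrying siderophores (-4.26, SE 0.63), at a mean of -2.45 (camera adjusted p = 1.42e-16; adjusted p = 0.120 with an estimated correlation). Of 19 adherens junction and desmosome genes 6 fell (1 higher and 8 lower adjusted over the list alone) at a mean of -0.92 (camera adjusted p = 5.56e-06; adjusted p = 0.162 with an estimated correlation). Of 10 spinous genes 2 fell, Serpinb2 and Sbsn (3 adjusted over the list alone), at a mean of -0.76 (camera adjusted p = 8.73e-04; adjusted p = 0.162 with an estimated correlation).

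Of 20 EMT and mesenchymal genes 5 rose and 1 fell (8 and 1 adjusted over the list alone), including Sparc by 2.03 (SE 0.23), at a mean of 1.21 (camera adjusted p = 3.83e-06; adjusted p = 0.352 with an estimated correlation). Of 16 Notch genes 3 rose (7 higher and 1 lower adjusted over the list alone): Jag2 by 1.59 (SE 0.23), the ligand Dll1 by 1.85 (SE 0.33) and the Notch-modifying enzyme Lfng by 2.32 (SE 0.42). Their mean was 0.63 (camera adjusted p = 8.80e-04; adjusted p = 0.162 with an estimated correlation). Of 29 actin and focal adhesion genes 3 rose and 1 fell (5 and 1 adjusted over the list alone) at a mean of 0.65 (camera adjusted p = 1.47e-04; adjusted p = 0.370 with an estimated correlation). The basal list had a mean of 0.52, with Dst up by 1.34 (SE 0.22) as the only passing gene by either count (camera adjusted p = 2.54e-04; adjusted p = 0.352 with an estimated correlation). No cell cycle gene passed at a mean of 0.69, or 0.38 without Ovol1/2 DKO replicate 1 (camera adjusted p = 3.26e-07; adjusted p = 0.571 with an estimated correlation). Interferon genes had a mean of -0.56, with Rsad2 lower at -2.22 (1 adjusted over the list alone; camera adjusted p = 5.31e-05; adjusted p = 0.162 with an estimated correlation). Wnt genes had a mean of 0.43, with Wnt3a up by 1.53 (SE 0.28; 3 higher adjusted over the list alone; camera adjusted p = 0.0447; adjusted p = 0.257 with an estimated correlation; 0.0602 with the block). Among 26 TGF-beta and BMP genes 4 rose and 2 fell, by either count, with Ltbp1 up by 2.15 (SE 0.34) and a mean of 0.34 (camera adjusted p = 0.0506). Schwann and Merkel markers had a mean of -0.70, with Krt8 lower at -1.72 (SE 0.28; 3 lower adjusted over the list alone; camera adjusted p = 9.18e-04; adjusted p = 0.352 with an estimated correlation). Thy1 rose by 1.90 (SE 0.22) among fibroblast markers and Pecam1 by 1.28 (SE 0.19) among endothelial markers, and neither list shifted (camera adjusted p = 0.518 and 0.754). P4ha1 rose by 1.71 and Adm fell by 1.57 among 20 hypoxia and glycolysis genes (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.483). Foxn1 fell by 3.36 among 22 hair follicle genes (1 lower adjusted over the list alone; mean -0.34, camera adjusted p = 0.149). Of the 6 genes with earlier reports of regulation by Ovol factors, Zeb1 and Vim rose and Id2 fell, by either count, at a mean of 1.25 (camera adjusted p = 0.0810). The p53 list held 1 gene lower adjusted over the list alone (camera adjusted p = 0.774), and the cholesterol synthesis and remaining cell type lists held no gene that passed by either count. Mean and median differed in sign for fibroblast (0.27 and -0.01), endothelial (0.14 and -0.02) and hypoxia and glycolysis genes (-0.12 and 0.02), and the skeletal muscle mean of 0.01 was positive while its test pointed down.

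The count of 628 also depended on the arrays, as did some list shifts. Without replicate 1 labelled Ovol1 KO the spinous mean was -0.38 (camera adjusted p = 0.0522), Serpinb2 and Sbsn lost the call, and the actin (mean 0.45, 0.0568) and Wnt (0.0664) shifts did not pass. The Wnt shift did not pass without Ovol1/2 DKO replicate 2 either (0.0965). Of the 61 named genes 17 had a lower group mean at or under 6.20, among them Foxn1, Rsad2 and Pecam1. Of the 61 named genes that passed, 23 did so in every setting that measured them, and Vim, Sparc and Cdh1 did not pass without replicate 1 labelled Ovol1 KO. Among the 23, Foxc2 and Marveld3 were not measured with dim genes left out. The count was 135 without replicate 1 labelled Ovol1 KO, 182 without Ovol1/2 DKO replicate 1, 154 without Ovol1/2 DKO replicate 2, and 1508 without both arrays that lacked Xist signal, chosen after the data were seen; with replicate number as a block it was 1022 (524 higher, 498 lower), including 621 of the 628.

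The comparisons with Ovol1/2 DKO share its arrays. Of their passing genes 122 were higher and 265 lower in both, against 1.54 and 5.33 for independent lists, which these are not. Across genes the differences of these comparisons correlated at r = 0.929 (covariance 0.420), where unchanged simulated groups sharing the same arrays gave 0.501 (0.0455), so part of the relation is built in. The differences of the arrays labelled Ovol1 KO and of Ovol1/2 DKO from control correlated across genes at r = -0.184, where unchanged simulated groups against the same controls gave 0.499. The simulations hold no changed gene in any group, while the changes in Ovol1/2 DKO widen its differences. An observed r is therefore not a like value to a simulated r here, and the covariance is the closer comparison. Genes are not independent replicates. The covariance was -0.0312 against 0.0452 simulated, a difference of -0.0764. With the smaller spread of the blocked fit, in which deviations shared by a replicate number cancel, the simulated covariance was 0.0276 and the difference -0.0588. The correlation was 0.318 without control replicate 1 and 0.0264 without control replicate 2. With 1 control array the simulated values rise too, to 0.666 and 0.667, so part of this change is built in. How much is not known, since these values are also for unchanged groups and no covariance is given for them.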

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

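The tests in this part were planned, apart from the choice to count unnamed probe sets separately, made after the results were seen. Among the 12146 probe sets that are unnamed here, and so stand outside the comparisons of genes, 2 were higher in Ovol1/2 DKO than in control when all probe sets were tested together, and 3 were higher in Ovol1/2 DKO than in the arrays labelled Ovol1 KO. Another 4 were lower in the latter comparison and 0 in the former.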

How the results depend on the processing

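The setting without both arrays that lacked Xist signal was chosen after the data were seen, and it leaves control and Ovol1 KO with 1 array each; the other settings were planned. A lone array of a group is assumed to vary like the groups that kept 2 arrays. Without both arrays that lacked Xist, that was Ovol1/2 DKO alone. The number of genes passing limma (403, 0 and 628) fell or rose by over 1.5 times in these settings. For Ovol1/2 DKO against control it was 155 with an offset of 64, 91 over all probe sets, 608 with array weights and 1395 without both arrays that lacked Xist. For Ovol1/2 DKO against the arrays labelled Ovol1 KO it was 311, 206 and 1508 for the offset, all probe sets and both arrays left out, and 1022 with the replicate block. For the arrays labelled Ovol1 KO against control it was 20 without both arrays. Leaving out 1 array gave 99 to 455, 135 to 831 and 0 to 3. The cause was not tested, and leaving arrays out both lowered and raised the counts of the comparisons with Ovol1/2 DKO.

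With an estimated correlation 0 lists passed in each comparison, from 15, 7 and 14. For the arrays labelled Ovol1 KO against control, epithelial identity (-0.081), spinous (-0.17), granular (-1.23) and actin (0.019) means changed sign without both arrays that lacked Xist. Leaving out 1 array turned the sign of means there over these ranges: spinous -0.19 to 0.56, granular -0.53 to 1.11, cell cycle -0.80 to 0.088, actin -0.37 to 0.030 and fibroblast -0.27 to 0.45. Given here are lists that passed over all arrays or in that setting. Means of some other lists turned too. The cell cycle mean in Ovol1/2 DKO against control ran from -0.11 to 0.78. The correlation of the differences from control, -0.184, was -0.193 after quantile normalization and -0.271 without dim genes, and ran from -0.299 to 0.318 with 1 array left out. With no replicate spread for it, 1 SD of the simulated correlation (0.00881) was the measure of a move. That SD comes from genes drawn independently, so it leaves out deviations that genes of an array share and is too small a measure. The cause was not tested.

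The replicate block kept all 51 and 61 passing named genes of the Ovol1/2 DKO comparisons and added Wnt3a, Dkk3 and Kdr against control, and it changed no list call beyond the 4 given with the lists. Over all settings the 3600 alternative values of named genes never changed sign with a call, 234 lost the call and 23 gained one. Of 1038 list values 12 changed sign with a call before or after (7 losing the call, 2 gaining one and 3 passing either way). Another 78 lost the call and 47 gained it. Sign changes of list means without a call were not counted. Zeb1 in Ovol1/2 DKO against control ranged from 4.21 to 5.29 (log2) and Epcam from -3.40 to -3.15. Between 5.54% and 6.50% of named genes per array lay below 5 on the log2 scale, where signal over background limits any difference. That cut is under the 6.20 called near background here, so the share of genes limited by background is larger.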

Other observations

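The tests on Ovol1, on late differentiation genes and on a pool of male and female mice were chosen after the results were seen, as was the grouping of genes by symbol; the test on genes that escape X inactivation was set before its values were read.

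Grouped by the stem of their symbols into 241 families, genes of the cornified envelope cluster were lower by camera in Ovol1/2 DKO than in control. The 13 Sprr genes had a mean log2 difference of -3.95, with 6 passing limma, all lower, and the 19 Lce genes one of -1.87 with 0 passing (camera adjusted p = 1.11e-15 and 9.65e-09). Their members share sequence and may be read by one another's probes. The 52 keratin genes had a mean of -0.57 with 7 lower, but a median of -0.06. The 10 Hoxa genes had a mean of 0.51 with 0 passing and the 11 Frizzled receptor genes one of 0.53 with Fzd2 passing (camera adjusted p = 0.0191 for each). These families kept their sign after quantile normalization and median centring (Sprr mean -3.89 and -3.96). The families given here were picked without a fixed rule, and others passed by camera too. Among those were Tmprss (mean -1.49, median -0.28, camera adjusted p = 6.93e-05), Fkbp (0.57, 0.32, 0.00486) and Cldn (-0.78, -0.12, 0.00761). For each family named here the adjusted p was 0.992 with an estimated correlation, and with it 0 of the fixed lists passed either.

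Ovol1 signal was not lower in the arrays labelled Ovol1 KO. An exchange of control and Ovol1 KO arrays would make the controls the low group only if the null allele gives no signal at this probe set, which is not known here. The lowest control array lay only -0.16 (log2) from the lowest array labelled Ovol1 KO, and neither group was low, so this signal cannot decide on an exchange. A transcript still made from the null allele and read by the probe set may account for the lack of a fall, since the arrays labelled Ovol1 KO lay 0.48 above control. The same null allele is in Ovol1/2 DKO, where Ovol1 was 4.18 lower, so that explanation also needs lower transcription there. Nothing here tells that apart from arrays that hold another genotype than their label, and an effect on Ovol1 of losing Ovol2, a loss that the Ovol2 signal did not show, was not tested. The female label of replicate 1 labelled Ovol1 KO was contradicted by its signal (Eif2s3y 13.80, Xist 4.54). That of replicate 2 was not (Eif2s3y 5.14, Xist 10.99). Sex signal does not read the genotype.

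Late differentiation genes were low in control replicate 1, with the granular and cornified list at 8.79 against 10.18 in replicate 2; replicate 2 labelled Ovol1 KO was nearly as low at 8.95, and on the first principal component control replicate 1 lay at -0.14, between the other such arrays (-43.4 to -37.0) and Ovol1/2 DKO (55.0 and 68.2). RNA of Ovol1/2 DKO cells mixed in would raise all genes higher there, and the list's fall needed a median share of 0.598 (quartiles 0.414 and 0.875). All 335 higher genes, tried first, gave 0.174 (0.0603 and 0.369) and missed the bound that was asked. Only then were the 115 genes over 4-fold higher taken, chosen without this array, and they gave 0.0643 (0.00524 and 0.183). A smaller share stays open. A batch shared by the replicate 1 arrays stays open too, since the list was 1.64 higher in replicate 1 than in replicate 2 labelled Ovol1 KO but lower in Ovol1/2 DKO (-0.68), 1 pair each. A less differentiated culture may be the cause: the list lay at -1.12 against the other 3 arrays outside Ovol1/2 DKO, epithelial identity at -0.28, the basal list at 0.20 and the cell cycle list at 0.83, a gap to epithelial identity below the 1 that was asked, so this stays open. Differences in genotype between the control mice were not tested.

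Control replicate 1 showed neither Xist nor Y-linked signal. A pool of male and female mice would show both, but the lower of Xist and Eif2s3y was 4.43. Cells with 1 X and no Y are a candidate explanation: 4 genes that escape X inactivation should then be lower, and they lay 0.20 above the lowest array with Xist. That bound was wrong for these arrays, since replicate 1 labelled Ovol1 KO, with Y-linked signal and no Xist, lay only -0.02 from the same array, so the genes do not resolve 1 X from 2. No other biological explanation was tested.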
